A study of Homo sapiens with 9 samples.

How the data were processed

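The data were 9 RNA-seq libraries of A375 cells, 3 per group, grouped by the treatment and title labels. Per the labels' protocols, total RNA was reverse transcribed with random hexamers, and the cDNA was amplified by PCR and circularised into single-strand circles as the final library. No label says that strand was marked, so reads of a gene and an overlapping antisense gene cannot be told apart. Reads were aligned with HISAT2 2.0.4 to hg38, per the submitters' processing notes. The counting tool and gene annotation are not given in the sources used here.

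The authors deposited 1 table of 18430 genes with 3 values per sample. Estimated counts per gene, as deposited, were not whole in 13.6% to 14.1% of the values of a library (tolerance 1e-06) and were rounded to whole numbers before the count tests. TPM and FPKM values, so named per the file headers, were the authors' normalized values, and TPM summed to between 999999 and 1000001 in each sample. TPM and FPKM were used for alternatives only, and the ratio of counts to FPKM for the effective length of each gene. The table held no row without counts in all samples. Of its gene identifiers 18153 matched the RefSeq gene table of GRCh38, from which coordinates and current symbols were taken, and 26 symbols that a spreadsheet had turned into dates were replaced through their identifier. The fixed list of genes encoded by the mitochondrial genome had no tested member.

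Library totals ranged from 14481020 to 16038475 estimated counts. Genes were kept by edgeR's filterByExpr with its defaults (13989 genes), libraries were scaled by TMM, and all 9 samples entered 1 fit of group means with edgeR 4.0.16 in R 4.3.3, with 6 residual degrees of freedom. Each contrast was tested two-sided with the quasi-likelihood F test, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. The biological coefficient of variation was 0.139. Where all libraries of a group were at 0, a fold is a lower bound against a floor of 3 counts over the group. For named genes with 1 to 3 counts, the ratio is given with an exact 95% binomial counting interval where the size of the change is printed. PCR reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only.

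The pipeline was tested on simulated counts with known changes. For vemurafenib against control it recovered 25.4% of 67 genes changed 1.5-fold, 86.6% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, with 11 false calls among 13529 genes. For cisplatin against control the shares were 28.4%, 92.5% and 98.5% (12 false calls among 13541), and for vemurafenib against cisplatin 29.9%, 85.1% and 100% (9 among 13519). Far fewer genes changed in these simulations than were called in the data, which makes the adjustment stricter, so the shares do not give the sensitivity in the data, where many called genes changed less than 2-fold.

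A set of 28 gene lists, the genes to be named, the design and the alternatives were chosen before the data were examined. Lists with at least 5 tested members (26) were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera passed 41 of the 78 list tests, and 0 passed with an estimated correlation. Blood markers had 2 tested genes (0 higher and 1 lower after vemurafenib, 1 and 0 after cisplatin, and 0 and 2 between the drugs) and were not tested as a list. Median and mean differed in sign only in lists that did not pass camera: the unfolded protein response in every comparison, melanocyte genes in both vemurafenib comparisons, growth factors and apoptosis regulators after cisplatin, and interferon-stimulated, class II and hypoxia genes between the drugs. The camera direction of fibroblast markers was upwards against controls where their median and mean were below 0. Named genes were, per comparison, the 5 largest rises and the 5 largest falls among called genes with a mean of at least 50 counts per library in the higher group and no overlap between groups, leaving out unnamed loci, up to 3 members of each core list and up to 2 of each other list that passed camera, and a fixed panel.

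Replicate numbers appear in the labels of each group. As a check of pairing, deviations of log2 CPM from the group mean were correlated across genes. For vemurafenib and control the same-numbered libraries gave 0.18, 0.14 and 0.18. The numbers were therefore taken as a possible pairing of these samples, from the data and not from any statement in the labels. The main fit of group means left this pairing out. Whether a length trend shared by libraries of the same number gave these correlations was not tested. The fit with replicate number as a block changed no call of a list or named gene in this comparison and moved no count of calls by more than 1.5 times. No pair of libraries was a duplicate: chi-square per degree of freedom between libraries of a group was 4.57 to 14.23, and 55.41 and 55.38 between vemurafenib replicate 1 and replicates 2 and 3.

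The alternatives were DESeq2's size factors (RLE), total counts as the only scaling, no filter beyond 1 count, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), log2(FPKM + 1) and log2(FPKM + 0.1), only the 6 libraries compared, the replicate block, counts thinned to the smallest library, and each library left out in turn. For lists they also included an estimated correlation and fry. Shared controls were addressed with 20 simulations in which all 3 groups were drawn from the control means with each gene's dispersion. Libraries were drawn independently, so any pairing by replicate number was left out. All columns of the table were used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.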

Results

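RNA was sequenced from 9 samples of A375, an established human melanoma cell line whose BRAF gene carries an activating mutation. The samples formed 3 groups of 3. Control cells were kept in normal culture. A second group received 10 µM vemurafenib, an inhibitor of mutant BRAF, for 3 days. The last group received 2 µM cisplatin, a platinum compound that crosslinks DNA, for 1 day. Both treated groups then returned to drug-free medium and were collected on day 7. The values of treated cells thus describe cells some days after the drug was withdrawn. The sample records used here hold a collection day for the treated libraries only. By its title, the study asked whether vemurafenib gives melanoma cells a secretory phenotype of senescence that differs from the canonical one. Dose, exposure time and the time without drug before collection differed between the drugs. Differences between the drugs cannot be told apart from differences in these. Library totals lay between 14481020 and 16038475 estimated counts, and 13989 genes were tested. The first principal component of log2 CPM (46.1% of the variance) parted vemurafenib from cisplatin libraries, and the second (40.1%) parted the controls from both. The third (5.8%) set vemurafenib replicate 1, at 39.1, apart from replicates 2 and 3, at -22.3 and -22.7. This library differed from the other two across genes with a trend in transcript length (Spearman's rho across genes -0.59, where genes are not independent replicates). Levels below are TMM-normalised CPM, the counts of a gene scaled to a common library size, as mean ± SD of the 3 libraries of a group. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

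Vemurafenib against control asked which genes differed from controls on day 7 after transient BRAF inhibition. Most of the classical secretory genes of senescence, the NF-kB-driven cytokines, chemokines and proteases, were lower in vemurafenib-treated cells. Of 20 tested members, 17 fell, 2 rose and 1 did not pass (the same counts adjusted over the list alone), with a median log2 change of -2.43. IL1A, an upstream cytokine of this programme, fell from 224.2 ± 61.8 to 18.4 ± 4.9 CPM (n = 3), and CXCL8, a neutrophil-attracting chemokine, from 912.4 ± 144 to 201.8 ± 53 CPM. CSF2 fell by 6.26 on the log2 scale (SE 0.47) and IGFBP3, an insulin-like growth factor binding protein, by 4.67 (SE 0.27). The 2 members that rose were CCL2, a monocyte-attracting chemokine, and the matrix protease MMP3. CCL2 went from 9.92 ± 2.83 to 218.4 ± 69.9 CPM. MMP3 rose by 4.99 on the log2 scale (SE 0.64) from near the floor. It was at 0 to 0.265 CPM in control libraries and 3.12 to 4.53 CPM in vemurafenib libraries. Its log2 change ranged from 1.56 to 6.52 over the alternatives. IL6 was below the count filter, with 25 counts summed over the 3 control libraries and 9 over the 3 vemurafenib libraries. A wider list of secreted factors, receptors and proteases had 54 falls and 20 rises among 99 tested genes (the same adjusted over the list alone). The camera adjusted p was 2.04e-08 for the first list and 5.23e-05 for the second. Both calls were lost with an estimated correlation (adjusted p = 0.114 for each).

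Interferon-stimulated genes moved the other way. Of 47 tested, 33 rose and 4 fell (34 and 4 adjusted over the list alone), with a median log2 change of 0.85 (camera adjusted p = 2.93e-08, adjusted p = 0.114 with an estimated correlation). IFIT2 rose from 2.44 ± 0.0215 to 26.4 ± 6.88 CPM, IFI44L by 3.39 and TRIM22 by 2.35 on the log2 scale. CXCL10 rose from 1.04 ± 0.419 to 5.04 ± 0.679 CPM. The members that fell were CXCL11, HERC5, ISG20 and CMPK2, chosen after their values were seen. Antigen presentation genes were higher as well. Class II genes had 11 rises and 1 fall among 12 (the same adjusted over the list alone, median 2.30, camera adjusted p = 2.04e-08, adjusted p = 0.232 with an estimated correlation). The member that fell was the lysosomal protease CTSS (chosen after its value was seen). HLA-DOA stood at 119.9 ± 13.5 against 5.57 ± 1.18 CPM. Class I presentation genes had 11 rises and no fall among 17 (12 and 0 adjusted over the list alone, median 0.51, camera adjusted p = 0.000208, adjusted p = 0.279 with an estimated correlation), among them HLA-F (log2 change 1.32) and HLA-E (1.28). HLA genes are close copies of each other, so the split of reads between them is uncertain.

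Proliferation genes were lower after vemurafenib, by a median log2 change of -1.07 for mitosis genes (39 of 40 fell, 40 adjusted over the list alone) and -0.62 for DNA replication genes (28 of 40 fell, 29 adjusted over the list alone). Camera gave adjusted p = 3.12e-16 and 1.47e-07, and 0.159 and 0.309 were the adjusted p values with an estimated correlation. MKI67, a proliferation marker, went from 528.8 ± 55.3 to 285.1 ± 43.5 CPM. The arrest genes did not pass camera as a group: of 21, 5 rose and 8 fell (5 and 9 adjusted over the list alone, camera adjusted p = 0.12). With fry, which does not compare a list with other genes, the list passed downwards (adjusted p = 0.000561). CDKN1A, which encodes the cell cycle inhibitor p21, was at 292.8 ± 24.4 against 326.9 ± 40.7 CPM (adjusted p = 0.334). CDKN1C fell by 3.34 on the log2 scale and KLF9 rose by 2.55. Among 29 p53 targets, 4 rose and 5 fell (the same adjusted over the list alone). The list's median log2 change was 0.00 (camera adjusted p = 0.884). LMNB1, whose loss is a common marker of senescence, fell by 0.92 (SE 0.12). It was among the 10 that fell of 12 lamin and chromatin genes lowered in senescence (the same adjusted over the list alone, camera adjusted p = 0.000311, adjusted p = 0.279 with an estimated correlation).

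The transcriptional output of ERK signalling was lower on day 7. Of 24 target genes 20 fell and none rose (22 fell and 1 rose adjusted over the list alone), with a median log2 change of -1.48 (camera adjusted p = 2.84e-11, adjusted p = 0.114 with an estimated correlation). DUSP6, an ERK phosphatase, went from 415.0 ± 22.9 to 168.2 ± 17.3 CPM. HMGA2 fell by 3.37 and EGR1 by 3.04 on the log2 scale. Melanocyte genes split, with 5 rises and 5 falls among 19 (the same adjusted over the list alone, camera adjusted p = 0.929, the median was -0.07 and the mean 0.30). MITF, the lineage transcription factor, rose by 1.20 (SE 0.17) and GPNMB by 2.07, while BCL2A1 was at 3.62 ± 1.03 against 20.5 ± 3.39 CPM. DCT, a pigment enzyme gene at 13:94436811-94549406 of GRCh38 (gene identifier 1638), rose from 0.0863 ± 0.0978 to 275.1 ± 103 CPM. Genes of the undifferentiated, inhibitor-tolerant state were also mixed, with 7 rises and 16 falls among 31 (the same adjusted over the list alone, camera adjusted p = 0.0604, past the threshold with total counts only, 0.0258, and with the filter of 1 CPM, 0.0386). The list's adjusted p ranged up to 0.138 over the alternatives that keep camera's preset correlation, and was 0.304 with an estimated correlation and 0.00562 with fry. NGFR, the neural crest nerve growth factor receptor at 17:49495293-49515008, rose from 9.19 ± 2.11 to 186.0 ± 23.9 CPM (log2 change 4.34, adjusted p = 4.59e-08), whereas the receptor kinase AXL fell by 1.22 and PDGFRA fell by 3.41.

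Hypoxia and glycolysis genes fell in 25 of 28 cases with 1 rise (26 and 1 adjusted over the list alone), by a median log2 change of -1.24 (camera adjusted p = 1.89e-13, adjusted p = 0.114 with an estimated correlation). CA9, a carbonic anhydrase induced by low oxygen, went from 234.6 ± 45.2 to 2.80 ± 2.3 CPM and NDRG1 from 695.4 ± 148 to 54.1 ± 6.93 CPM. Lysosome and autophagy genes had 15 rises and 8 falls among 32 (the same adjusted over the list alone, camera adjusted p = 0.0155, adjusted p = 0.304 with an estimated correlation), with the protease CTSK up by 2.96. Growth factor ligands and receptors had 18 falls and 8 rises among 35 (the same adjusted over the list alone, camera adjusted p = 0.00746, adjusted p = 0.343 with an estimated correlation). The EGFR ligand AREG fell by 3.83 and FGF1 rose by 3.60. DNA repair genes had 16 falls and 2 rises among 36 (the same adjusted over the list alone, camera adjusted p = 0.0216, adjusted p = 0.316 with an estimated correlation). The list missed the threshold without vemurafenib replicate 1 (adjusted p = 0.0506, with a range from 0.00875 to 0.0506 over the alternatives that keep camera's preset correlation, and 0.00132 with fry). Without that library 6 rose and 18 fell. Epithelial markers had 5 falls and 1 rise among 6 (the same adjusted over the list alone, camera adjusted p = 0.0107, adjusted p = 0.304 with an estimated correlation), led by KRT14 (0.463 ± 0.244 against 4.41 ± 1.11 CPM) and CLDN4 (3.85 ± 0.991 against 24.4 ± 3 CPM). Of 37 ribosomal protein genes 1 fell, RPS6, and none passed adjusted over the list alone (camera adjusted p = 0.042, adjusted p = 0.763 with an estimated correlation). Without vemurafenib replicate 1, 32 fell (adjusted p = 3.66e-07), and the list's call was lost without control replicate 1 or 2 or vemurafenib replicate 2 or 3 (0.152, 0.11, 0.33 and 0.285). The call of RPS6 (2127 ± 330 against 2842 ± 298 CPM) was lost without control replicate 1 or 2, vemurafenib replicate 2 or 3 or cisplatin replicate 2 (0.113, 0.0978, 0.093, 0.0856 and 0.0524). Its adjusted p ranged from 0.00202 to 0.15 over the alternatives. Matrix genes (16 rises and 11 falls among 37, camera adjusted p = 0.193), NRF2 targets (9 and 3 among 24, 0.199) and cholesterol synthesis (3 and 9 among 23, 0.19) did not pass. Nor did the unfolded protein response (4 and 5 among 24, 0.884), apoptosis regulators (5 and 8 among 25, 0.286) or markers of fibroblasts (3 and 2 among 9, 0.68) and endothelium (0 and 2 among 6, 0.231). Adjusted over each of these lists alone the counts were the same, except 12 falls for matrix genes and 9 for apoptosis regulators. Rises without vemurafenib replicate 1 numbered 7 for the unfolded protein response, 1 for ERK output and 1 for DNA replication.

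By fitted change, which gives no firm order where a group has few counts, the largest rises included ANGPTL7, DCT, PCSK2, AQP4 and FGL2. ANGPTL7, an angiopoietin-like secreted protein, had no count in any control library and was at least 721-fold higher in vemurafenib cells, with 47.4 ± 36.2 CPM. The floor was 3 counts over the group. On the same floor AQP4, a water channel of glia, was at least 93.7-fold and FGL2 at least 68.0-fold higher. PCSK2, a prohormone convertase, had a ratio of 1140 (95% counting interval 317 to 9460). Among the largest falls by fitted change were ZP4, HES2, SPRR2D, PLEK2 and CA9, with SPRR2D at 21.2 ± 1.88 CPM in controls and 0.168 ± 0.146 after the drug. In all, 3082 genes were higher and 3200 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, of which 971 and 1407 changed by at least 1 on the log2 scale. The 3 values of one group did not overlap those of the other for 52.8% of genes, where chance gives 10%. With total counts as the only scaling, 60.0% of the called genes were higher, against 49.1% with TMM. On the log2(TPM + 1) scale 59.3% were.

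**Figure D1:**
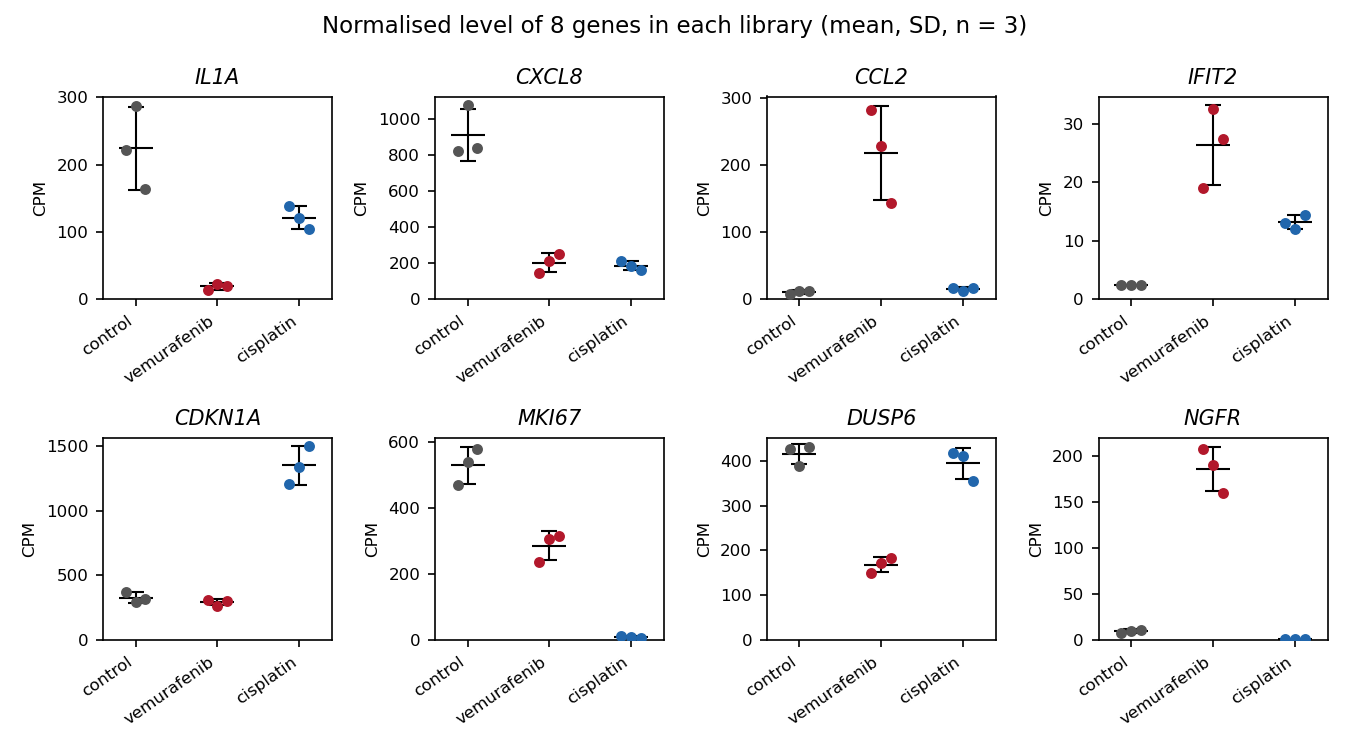
Each panel shows 1 gene, with CPM on a linear y axis starting at 0, the 3 groups on the x axis, points for libraries, a dash for the group mean and a bar for the SD (n = 3). IL1A, CXCL8 and MKI67 were lower after both drugs and IFIT2 higher after both, CCL2 and NGFR were high after vemurafenib (218.4 and 186.0 CPM), DUSP6 was low after vemurafenib (168.2 CPM), and CDKN1A was high after cisplatin (1350 CPM).

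Cisplatin against control served as a DNA-damage reference for the same readout. Of the fixed lists, those of proliferation genes had the lowest medians. All 40 mitosis genes and all 40 DNA replication genes fell (the same adjusted over the list alone), by median log2 changes of -5.41 and -2.98 (camera adjusted p = 1.3e-35 and 7.29e-27, adjusted p = 0.0573 and 0.0663 with an estimated correlation). KIF20A, a mitotic kinesin, went from 156.9 ± 14.9 to 1.12 ± 0.486 CPM (n = 3), HMMR from 99.6 ± 7.12 to 0.771 ± 0.119, and MKI67 from 528.8 ± 55.3 to 8.81 ± 2.44. LMNB1 fell from 135.8 ± 17.8 to 4.62 ± 0.624 CPM and HMGB2 by 4.99 on the log2 scale, and all 12 lamin and chromatin genes fell (the same adjusted over the list alone, camera adjusted p = 5.92e-11, adjusted p = 0.0663 with an estimated correlation). DNA repair genes had 22 falls and 4 rises among 36 (the same adjusted over the list alone, median -1.18, camera adjusted p = 1.95e-06, adjusted p = 0.0743 with an estimated correlation). RAD54L and BLM, which act in homologous recombination, had log2 changes of -3.97 and -3.94. The 4 that rose were ATR, XPC, DDB2 and POLH, chosen after their values were seen.

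Targets of p53 rose. Of 29, 23 rose and none fell (26 and 0 adjusted over the list alone), with a median log2 change of 1.04 (camera adjusted p = 2.29e-11, adjusted p = 0.0573 with an estimated correlation). CDKN1A went from 326.9 ± 40.7 to 1350 ± 148 CPM (log2 change 2.05, adjusted p = 2.81e-07). The ceramidase gene ACER2 went from 8.94 ± 0.287 to 47.8 ± 0.474 CPM, and EDA2R rose by 1.70. GDF15 rose by 0.81 (SE 0.24, adjusted p = 0.0159). Its call was lost without control replicate 1, control replicate 2 or cisplatin replicate 3 (adjusted p = 0.0681, 0.0571 and 0.0765, with a range from 0.00242 to 0.0765 over the alternatives). The arrest genes split into 6 rises and 7 falls among 21 (the same adjusted over the list alone, camera adjusted p = 0.733), where FOXO1 rose by 2.10 and CDKN2C fell by 2.32. Lysosome and autophagy genes had 25 rises and 2 falls among 32 (26 and 2 adjusted over the list alone, median 0.76, camera adjusted p = 9.59e-10, adjusted p = 0.0573 with an estimated correlation), among them MAN2B1 at 616.2 ± 6.78 against 204.3 ± 21.2 CPM.

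The canonical secretory genes fell after cisplatin too, with 13 falls and 1 rise among 20 (the same adjusted over the list alone, median -1.07, camera adjusted p = 8.32e-05, adjusted p = 0.175 with an estimated correlation). CXCL8 went to 184.5 ± 26.3 CPM from 912.4 ± 144 in controls, CXCL1 fell by 2.52, CXCL2 fell by 2.95, CSF2 fell by 4.45 and IL1A fell by 0.89 (SE 0.22). CCL2 was at 15.0 ± 2.51 against 9.92 ± 2.83 CPM (adjusted p = 0.091). It passed in 7 of 21 alternatives, among them without vemurafenib replicate 1 (adjusted p = 0.0473) and without vemurafenib replicate 3 (0.0329), with a range from 0.0221 to 0.296. IL6 had 2 counts over the 3 cisplatin libraries and 25 over the controls. The wider secretory list had 38 falls and 17 rises among 99 (38 and 18 adjusted over the list alone, camera adjusted p = 0.0383, adjusted p = 0.309 with an estimated correlation). The gelatinase MMP9 fell by 5.46. Without vemurafenib replicate 1 the list's adjusted p was 0.0707, and it ranged from 0.0159 to 0.0707 over the left-out libraries. Interferon-stimulated genes had 30 rises and 2 falls among 47 (31 and 2 adjusted over the list alone, median 0.88, camera adjusted p = 9.85e-08, adjusted p = 0.0663 with an estimated correlation). TRIM22 rose by 3.63, IFI6 by 2.52 and IFIT2 by 2.43. CXCL10 was at 0.699 ± 0.27 against 1.04 ± 0.419 CPM (adjusted p = 0.259). Class II genes had 11 rises and 1 fall among 12 (the same adjusted over the list alone, median 2.30, camera adjusted p = 1.94e-08, adjusted p = 0.169 with an estimated correlation). Class I genes had 12 rises and no fall among 17 (the same adjusted over the list alone, median 0.51, camera adjusted p = 0.000164, adjusted p = 0.206 with an estimated correlation), among them HLA-C at 727.0 ± 58.8 against 295.3 ± 25 CPM.

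ERK output genes had 8 falls and 2 rises among 24 after cisplatin (the same adjusted over the list alone, camera adjusted p = 0.131). DUSP6 was at 394.6 ± 34.6 against 415.0 ± 22.9 CPM (adjusted p = 0.62). Genes of the undifferentiated state had 19 falls and 3 rises among 31 (the same adjusted over the list alone, median -0.73, camera adjusted p = 0.000177, adjusted p = 0.0663 with an estimated correlation). LOXL2 fell by 3.65, FN1, which encodes fibronectin, fell by 3.14 and NGFR fell by 3.33. Melanocyte genes had 7 rises and 5 falls among 19 (the same adjusted over the list alone, camera adjusted p = 0.625), with MITF at 37.3 ± 3.89 against 35.8 ± 1.54 CPM (adjusted p = 0.804). Hypoxia and glycolysis genes had 25 falls and no rise among 28 (the same adjusted over the list alone, median -1.21, camera adjusted p = 2.18e-12, adjusted p = 0.0573 with an estimated correlation). CA9 was at 2.42 ± 0.339 CPM and BNIP3 at 65.5 ± 1.03 against 434.7 ± 79.5 CPM. Of 37 ribosomal protein genes 5 fell, RPS2 and RPSA among them, and none passed adjusted over the list alone (camera adjusted p = 0.00609, adjusted p = 0.758 with an estimated correlation). Without vemurafenib replicate 1, a library outside this contrast, 23 fell (adjusted p = 0.000162), and the list's call was lost without cisplatin replicate 3 (0.0559). NRF2 targets had 10 falls and 4 rises among 24 (camera adjusted p = 0.0826). They passed with the filter of 1 CPM (0.0436) and without control replicate 2 (0.0354) or cisplatin replicate 3 (0.0353), with a range from 0.0353 to 0.145 over the alternatives that keep camera's preset correlation, 0.421 with an estimated correlation and 0.00162 with fry. Matrix genes (11 rises and 13 falls among 37, camera adjusted p = 0.403), growth factors and receptors (11 and 10 among 35, 0.854) and the unfolded protein response (11 and 9 among 24, 0.625) did not pass. Nor did cholesterol synthesis (3 and 8 among 23, 0.445), apoptosis regulators (5 and 7 among 25, 0.8) or markers of fibroblasts (3 and 2 among 9, 0.81), epithelium (2 and 3 among 6, 0.625) and endothelium (1 and 0 among 6, 0.605). Adjusted over each of these lists alone the counts were the same, except 12 and 15 for matrix genes, 12 and 9 for the unfolded protein response, 7 and 7 for apoptosis regulators and 3 and 3 for fibroblast markers. Rises without vemurafenib replicate 1 numbered 10 for apoptosis regulators, 4 for ERK output, 2 for canonical secretory genes and 2 for endothelial markers. Among the largest rises by fitted change were F5, coagulation factor V (43.5 ± 11.7 against 0.239 ± 0.0979 CPM), CST1 (ratio 180, 95% counting interval 31.9 to 7150), PDYN, MUC7 (74.2 ± 3.43 against 0.714 ± 0.467 CPM) and HLA-DQB2. CST1 and HLA-DQB2 have close copies, so reads shared with them leave their levels uncertain. In all, 3181 genes were higher and 3290 lower by edgeR's quasi-likelihood test, 1116 and 1301 of them by at least 1 on the log2 scale. Leaving out vemurafenib replicate 1, which enters the fit but not this contrast, gave 4220 higher and 4422 lower genes. Groups did not overlap for 67.0% of genes, where chance gives 10%.

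**Figure D2:**
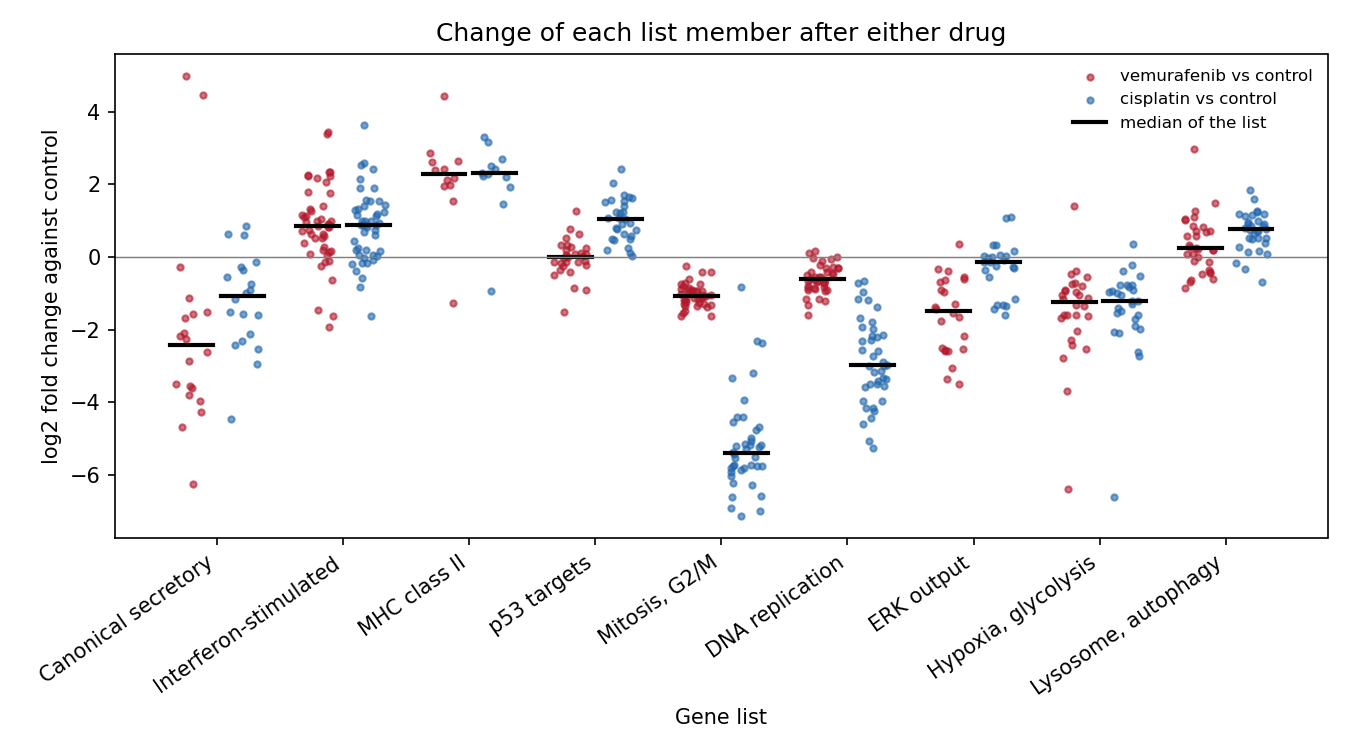
Each point is 1 tested member of a fixed gene list, with its log2 fold change against control on the y axis, the list on the x axis, the drug as the colour and the median of the list as a black line. Canonical secretory genes lay mostly below 0 after both drugs (medians -2.43 and -1.07), interferon-stimulated and MHC class II genes above 0 after both, p53 targets above 0 after cisplatin (median 1.04) and around 0.00 after vemurafenib, and mitosis genes far lower after cisplatin (-5.41 against -1.07).

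Vemurafenib against cisplatin compared the 2 treatments directly, each with its own dose, exposure and time without drug. Mitosis genes were higher in vemurafenib than in cisplatin cells for all 40 members (median log2 difference 4.42) and replication genes for 38 of 40 (median 2.25), the same counts adjusted over the list alone. MKI67 was at 285.1 ± 43.5 against 8.81 ± 2.44 CPM (n = 3). Camera adjusted p was 5.51e-32 and 6.53e-22, and with an estimated correlation adjusted p = 0.0929 and 0.15. Of 29 p53 targets 24 were lower in vemurafenib cells and none higher (26 and 0 adjusted over the list alone, median -0.77, camera adjusted p = 1.52e-11, adjusted p = 0.0929 with an estimated correlation). CDKN1A was at 292.8 ± 24.4 against 1350 ± 148 CPM. LMNB1 was higher by 3.95, and all 12 lamin and chromatin genes were higher (the same adjusted over the list alone, camera adjusted p = 5.48e-09, adjusted p = 0.0929 with an estimated correlation). ERK output genes were lower for 19 of 24 and higher for 2 (the same adjusted over the list alone, median -1.24, camera adjusted p = 1.05e-08, adjusted p = 0.15 with an estimated correlation), among them EPHA4, IER3 and DUSP6.

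Canonical secretory genes were lower in vemurafenib than in cisplatin cells for 11 of 20 members and higher for 3 (12 and 3 adjusted over the list alone, median -1.12, camera adjusted p = 0.0122, adjusted p = 0.374 with an estimated correlation). IGFBP3 was at 64.8 ± 24.6 against 1355 ± 225 CPM and IL1A at 18.4 ± 4.9 against 120.6 ± 17.3 CPM, whereas CXCL8 was not told apart (log2 difference 0.13, SE 0.19, adjusted p = 0.61). The 3 members that were higher were MMP3, CCL2 and CXCL1. CCL2 differed by 3.86 (SE 0.27) and CXCL1, named after its value was seen, by 1.01. In the wider list 33 genes were lower and 24 higher among 99 (39 and 24 adjusted over the list alone, camera adjusted p = 0.118). AREG, CD55, which inhibits complement, and the neurosecretory gene VGF had log2 differences of -6.40, -5.64 and -5.18. TIMP1, an inhibitor of matrix proteases, stood at 595.4 ± 149 against 9143 ± 1390 CPM. Interferon-stimulated genes had 12 higher and 15 lower among 47 (13 and 17 adjusted over the list alone, camera adjusted p = 0.807, median -0.11 and mean 0.04). CXCL10 was higher by 2.83 and IFITM1 by 1.71, and HERC5 was at 1.81 ± 0.243 against 5.47 ± 0.226 CPM. Class I genes had 4 higher and 4 lower among 17 (the same adjusted over the list alone, camera adjusted p = 0.72). Class II genes had 1 higher among 12, HLA-DOA, chosen after its value was seen (the same adjusted over the list alone, camera adjusted p = 0.856, median -0.07 and mean 0.03). Without vemurafenib replicate 1, 7 class I genes were lower and 3 higher, and 3 class II genes were lower and 1 higher.

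Matrix genes were higher in vemurafenib cells for 18 of 37 members and lower for 6 (18 and 7 adjusted over the list alone, camera adjusted p = 0.0123, adjusted p = 0.343 with an estimated correlation), with POSTN, periostin, higher by 4.35. Lysosome and autophagy genes were lower for 18 of 32 and higher for 2 (18 and 4 adjusted over the list alone, camera adjusted p = 0.000911, adjusted p = 0.196 with an estimated correlation). NRF2 targets were higher for 13 of 24 and lower for 1, the transporter gene ABCC3 (the same adjusted over the list alone, camera adjusted p = 0.00282, adjusted p = 0.196 with an estimated correlation). DNA repair genes were higher for 23 of 36 and lower for 4 (the same adjusted over the list alone, camera adjusted p = 5.41e-05, adjusted p = 0.167 with an estimated correlation). Growth factor ligands and receptors were lower for 18 of 35 and higher for 7 (19 and 7 adjusted over the list alone, camera adjusted p = 0.01, adjusted p = 0.382 with an estimated correlation). HGF was at 0.228 ± 0.141 against 4.98 ± 0.621 CPM. Epithelial markers were lower for 5 of 6 (the same adjusted over the list alone, camera adjusted p = 0.0115, adjusted p = 0.321 with an estimated correlation), with KRT8 at 13.7 ± 1.79 against 44.4 ± 5.4 CPM. Arrest genes had 4 higher and 8 lower of 21 (the same adjusted over the list alone, camera adjusted p = 0.0809, 0.0424 without cisplatin replicate 3, with a range from 0.0424 to 0.157 over the alternatives that keep camera's preset correlation, 0.279 with an estimated correlation and 0.000165 with fry). Melanocyte genes (6 and 6 of 19, 6 and 7 adjusted over the list alone), undifferentiated-state genes (14 and 8 of 31, 16 and 9 adjusted over the list alone) and hypoxia genes (7 and 6 of 28, the same adjusted over the list alone) did not pass camera (adjusted p = 0.807, 0.187 and 0.807). Nor did the unfolded protein response (5 and 8 of 24, adjusted p = 0.351), cholesterol synthesis (3 and 6 of 23, 0.518), apoptosis regulators (5 and 9 of 25, 0.302), ribosomal proteins (2 and 0 of 37, 0.636) or fibroblast markers (2 and 3 of 9, 0.855). Endothelial markers (1 and 5 of 6, camera adjusted p = 0.0601) had adjusted p = 0.0466, 0.0479 and 0.0442 without vemurafenib replicate 3, cisplatin replicate 2 or cisplatin replicate 3 and 0.0462 with total counts only. Their adjusted p ranged up to 0.108 over the alternatives that keep camera's preset correlation, and was 0.196 with an estimated correlation and 0.000318 with fry. Adjusted over each of these lists alone the counts were the same, except 5 and 9 for the unfolded protein response and 0 and 0 for ribosomal proteins. With vemurafenib replicate 1 left out, ribosomal proteins had 1 higher and 4 lower, and 4 lysosome and autophagy genes were higher. The largest differences included ANGPTL7 (ratio 2080, 95% counting interval 373 to 82200), SEC14L5, DCT, PRIMA1 and TNN on the vemurafenib side. On the cisplatin side were CST1, at least 62.3-fold higher than in vemurafenib cells, PDYN, SYT12, SLCO2B1 and CST2, where CST1 and CST2 share sequence. In all, 3214 genes were higher and 2905 lower in vemurafenib than in cisplatin cells, and 54.0% of genes had groups that did not overlap, where chance gives 10%.

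The overlap of both drugs' changes was counted among the same 13989 genes. Both drugs raised 1588 genes and lowered 1721, where independent lists of these sizes would share 701 and 753. In all, 463 genes were called in opposite directions, where independent lists would give 1452. Among the fixed lists, 26 of 47 interferon-stimulated genes rose in both, 12 of 20 canonical secretory genes fell in both, and 24 of 28 hypoxia and glycolysis genes fell in both. Both comparisons used the same 3 controls. Simulated unchanged groups shared no calls in 20 simulations but gave a Pearson correlation of log2 changes of 0.498, against 0.449 observed, with a covariance of 0.024 against 0.482, a difference of 0.458. The simulated libraries were independent draws, without the possible pairing by replicate number. No gene differed between the simulated groups, so the lack of shared calls was given by the setting. It does not show how much the shared controls add to shared calls where many genes are called, as in the data. The 3 controls could not be split into sets of 2, so part of the excess may come from the shared controls.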

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

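All 3 tests of vemurafenib replicate 1, both tests of class II genes, and the tests of dividing cells and of shared controls for the hypoxia genes were chosen after the results were seen, unlike the splits of the samples. The length test of the hypoxia genes was recorded as written before, though the fall it addresses is itself a main result.

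A rule picked genes with called changes of at least 1 on the log2 scale in opposite directions after the 2 drugs. It also required a direct vemurafenib against cisplatin difference past the threshold, so passing that test was part of the choice. Among the named genes 12 met the rule (edgeR, highest adjusted p of the direct difference 1.61e-05), and 130 genes did in the whole table. Higher in vemurafenib and lower in cisplatin than in controls were NGFR (direct log2 difference 7.67), SEC14L5 (9.51, a fitted value, with a ratio of 989 and a 95% counting interval of 177 to 39100), the cell cycle inhibitor CDKN2C (3.80) and malic enzyme ME1 (2.16). Lower in vemurafenib and higher in cisplatin were AREG (-6.40), TIMP1 (-3.94), ACER2 (-3.93), HGF (-4.39), EPHA4 (-3.67), SYT12 (-7.80, a fitted value, with a ratio of 309 and an interval of 55.0 to 12200), CD55 (-5.64) and SLC45A2 (-4.53).

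Vemurafenib replicate 1 stood apart from replicates 2 and 3. Its log2 ratio to them fell with effective transcript length (rho -0.59 across 13989 genes). The median ratio was 0.40 in the lowest quartile of length and -0.44 in the highest. In control and cisplatin libraries the same measure lay between -0.16 and 0.17. Replicate 1 had the lowest value in both of these groups, -0.16 in each. Whether part of the trend goes with replicate number was not tested. A length-dependent difference in RNA integrity or library preparation in vemurafenib replicate 1 is a possible explanation only. Removing the trend lowered the SD of the ratio from 0.544 to 0.455, so length left most of the spread. Control RNA mixed into that library is argued against: 46 genes at least 16-fold lower in replicates 2 and 3 than in controls allowed a median control share of -0.65% (quartiles -1.66 and 0.09), a test that replaced a correlation with the drug response (r across genes -0.09) too near its bound to decide. Whether it had also moved further along the drug response stays open, since its difference from one replicate correlated with the response of the other at -0.09 and 0.11, opposite in sign.

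Hypoxia and glycolysis genes fell by similar medians after both drugs, -1.24 and -1.21. Length bias is argued against, since with the length trend removed the medians were -1.30 and -1.20. A graded loss with dividing cells is argued against as well, because mitosis genes fell far more after cisplatin while the hypoxia members differed between the drugs by a median of 0.05 (quartiles -0.41 and 0.31). The members' 2 changes correlated at 0.83 across genes, which the state of the shared controls (for example denser cultures with less oxygen) may give, and so may a change made by both drugs. These cannot be told apart with 1 set of controls.

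HLA class II genes rose after both drugs, of which HLA-DOA rose further after vemurafenib (direct log2 difference 1.11, edgeR adjusted p = 0.000957) and HLA-DQB2 further after cisplatin (-2.59, edgeR adjusted p = 8.52e-05). Reads moving between their near-identical copies are argued against: the CPM summed over 15 class II genes was 4.73 times the control value after vemurafenib and 4.91 times after cisplatin, with each treated library at 2960 or more and each control at 751 or less. CIITA, the regulator of these genes and itself a member of the fixed class II list, rose by 2.19 and 2.29 on the log2 scale. Its rise was thus already part of the list's result, and its activity is a candidate explanation only. The state of the shared controls was not tested for these genes and stays open.

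The 6 libraries of each comparison can be split 10 ways, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many called genes: 6282 for vemurafenib against control, 6471 for cisplatin against control and 6119 for vemurafenib against cisplatin, and the highest of the other splits gave 0 in each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, including those that part as many pairs of same-numbered vemurafenib and control libraries. At an unadjusted p under 0.05 the other splits gave 55 to 1156, 32 to 176 and 84 to 1096 genes. Every other split puts libraries of both groups on each side, so the difference between the groups widens the spread within a side. The values of 0 follow largely from this layout and decide nothing about chance or pairing.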

How the results depend on the processing

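Alternatives were planned except the list counts without vemurafenib replicate 1, added after seeing the data. Of 4011 values of named genes under the alternatives, 12 lost and 7 gained the threshold (RPS6, GDF15 and CCL2). Direction changed for 4 of them and for 19 of 1170 list values, 0 of which passed the threshold before or after. These were GDF15 in vemurafenib against control (-0.35 to 0.05 over left-out libraries), CXCL8 in vemurafenib against cisplatin (-0.08 to 0.32) and DUSP6 in cisplatin against control (0.00 with log2(TPM + 1)). Among lists in vemurafenib against control the adjusted p ranged over left-out libraries from 0.672 to 0.992 for p53 targets, 0.733 to 0.998 for melanocyte genes (0.919 with total counts only) and 0.681 to 0.998 for the unfolded protein response (0.601 with fry). In vemurafenib against cisplatin it ranged from 0.645 to 0.947 for interferon-stimulated, 0.406 to 0.942 for class II, 0.7 to 0.97 for melanocyte (0.241 with fry) and 0.0622 to 0.857 for ribosomal genes and 0.554 to 0.974 for fibroblast markers. In cisplatin against control fry gave 0.722 for growth factors and 0.743 for apoptosis regulators. Counts of higher and lower genes stayed within 1.5 times in all settings. At a change of at least 1 log2, log2(FPKM + 1) gave 591 higher and 691 lower genes for vemurafenib against control, 521 and 727 for cisplatin against control, and 707 and 654 for vemurafenib against cisplatin, and log2(TPM + 1) gave 856 lower, 716 higher and 841 lower, and 836 lower. The pseudocount of 1 shrinks low genes, and log2(FPKM + 0.1) stayed within 1.5 times. With an estimated correlation adjusted p = 0.114 for the canonical, wider secretory and interferon lists and 0.159 for mitosis in vemurafenib against control. In the same order they were 0.175, 0.309, 0.0663 and 0.0573 in cisplatin against control, with 0.0573 for p53 targets, and 0.374 for canonical secretory and 0.0929 for p53 and mitosis in vemurafenib against cisplatin. fry, which does not compare a list with other genes, passed the wider secretory list there (0.000973, against 0.0563 to 0.205 by camera without 1 library). Across all comparisons fry passed 16 list tests that camera did not, in the same direction, and lost 2. Leaving out each library gave the wider secretory list in cisplatin against control adjusted p = 0.0159 to 0.0707, past 0.05 only without vemurafenib replicate 1, and the cause was not tested. Called genes ranged over left-out libraries from 2378 to 3716 higher and 2661 to 3956 lower for vemurafenib against control, and 6009 of 6282 calls remained without vemurafenib replicate 1, in the same direction. For cisplatin against control they ranged from 2556 to 4220 higher and 2665 to 4422 lower. For vemurafenib against cisplatin they ranged from 2433 to 3755 higher and 2334 to 3402 lower. The highest counts in each comparison came without vemurafenib replicate 1, where cisplatin against control had 8642 calls against 6471. Genes changed alike by at least 1 log2 numbered 417 up and 516 down, with 130 opposite, fewer by construction. The replicate block gave 3195 higher and 3348 lower genes for vemurafenib against control, and 3369 and 3488 for cisplatin against control and 3346 and 3096 for vemurafenib against cisplatin, where same-numbered libraries correlated at 0.21, 0.08 and 0.13, and 0.17, 0.01 and 0.10. Each cisplatin library correlated best with the control of its own number, a hint from the data only, and no call of a list or named gene changed. Thinning each library to 14481020 counts moved no count by 1.5 times.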

Other observations

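Of the 10 lists of this part, 9 were chosen after the results were seen, as was the glial test but not the chromosome test, and 1 repeated the fixed list of cholesterol synthesis genes and counts only in the adjustment. The lists were tested with camera in each comparison. Schwann cell and neural crest glial genes were higher after vemurafenib, with 15 rises and 5 falls among 23 tested against controls (median 1.68, camera adjusted p = 6.06e-05, adjusted p = 0.117 with an estimated correlation) and 17 higher and 4 lower against cisplatin (median 1.34, camera adjusted p = 4.41e-05, adjusted p = 0.21 with an estimated correlation). GFRA1 rose by 4.16, S100B by 4.15 and FOXD3 by 3.18, while ITGB4 fell by 5.49 on the log2 scale. GFRA2 rose from a mean of 0.0653 to 2.29 CPM, with too few control counts for a firm size (fitted log2 change 4.97). After cisplatin the list had 8 rises and 8 falls (camera adjusted p = 0.814). Notch pathway genes fell after both drugs, with 9 falls and 1 rise of 12 after vemurafenib (camera adjusted p = 0.00118, adjusted p = 0.0822 with an estimated correlation) and 8 falls and 0 rises after cisplatin (0.0235, adjusted p = 0.22 with an estimated correlation), among them JAG2 (-3.58 and -1.52) and HES1 (-1.80 and -1.25). Wnt targets had 6 falls and 2 rises of 11 after vemurafenib and 7 falls and 1 rise after cisplatin (camera adjusted p = 0.0368 and 0.0235, adjusted p = 0.225 and 0.22 with an estimated correlation), with AXIN2 at log2 changes of -2.19 and -2.46.

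Targets of TGF-beta had 11 falls and 4 rises of 19 after vemurafenib, with POSTN up by 4.94, and 7 falls and 0 rises after cisplatin (camera adjusted p = 0.0368 and 0.0459, adjusted p = 0.201 and 0.22 with an estimated correlation), and targets of YAP and TEAD had 10 falls and 4 rises of 21, and 9 and 1 (camera adjusted p = 0.0368 and 0.0654, adjusted p = 0.242 and 0.345 with an estimated correlation). ATF4 targets had 15 falls and 1 rise of 22 after cisplatin (camera adjusted p = 0.00274, adjusted p = 0.22 with an estimated correlation), with the serine synthesis gene PHGDH at -2.57, against 9 falls and 3 rises after vemurafenib (camera adjusted p = 0.284). Of these genes 12 of 22 were higher and 1 lower in vemurafenib than in cisplatin cells (camera adjusted p = 0.0448, adjusted p = 0.369 with an estimated correlation). Complement genes had 7 rises and 2 falls of 15 after vemurafenib and 8 rises and 2 falls after cisplatin and did not pass (camera adjusted p = 0.0687 and 0.0641), with C1S at log2 changes of 4.16 and 1.54 and CD55 at -2.93 and 2.71. Synapse genes and autophagy genes passed in no comparison, with the lowest camera adjusted p at 0.062 and 0.0654.

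A hypothesis was that a glial gene programme rose as a group after vemurafenib and was not carried by the genes that first drew attention. The list's adjusted p by limma's camera was 6.06e-05, and without the 4 genes that a fixed list also holds (NGFR, SOX10, ERBB3 and SOX2) 13 of the remaining 19 rose and 5 fell (median 1.83, unadjusted p = 6.71e-05 by limma's camera). Of these 4, NGFR and SOX2 had risen, while SOX10 and ERBB3 had not passed, so dropping the latter could not weaken the result. The removal shows only that NGFR and SOX2 did not carry the list. The list was written with NGFR, AQP4 and DCT already seen, and its call was lost with an estimated correlation, so a glia-like shift remains a possible explanation only.

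A second hypothesis, that a drug selected cells with other chromosome copy numbers, predicted a chromosome whose genes moved together. The median log2 change of a chromosome differed from that of all genes by -0.146 at most, for the 191 tested genes of chromosome 18 in vemurafenib against control, which argues against a whole-chromosome change in most cells. Chromosome 18 also had the largest deviation in cisplatin against control, -0.131, and lay at -0.013 in vemurafenib against cisplatin. Whether this came from the shared controls was not tested. Smaller segments and minor clones were not tested.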
